A study of Homo sapiens with 6 samples.

How the data were processed

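Gene expression was measured with Affymetrix whole-transcript arrays in TPC-1 cells, an established line from a human papillary thyroid carcinoma. There were 6 arrays, 3 from cells transfected with an siRNA against SMAD3 and 3 from cells transfected with a control siRNA. Per the labels' protocols, 25 pmol of siRNA was delivered with 4.5 ul of a lipid reagent to cells at about 85% confluence, RNA was taken after 24 h and treated with DNase, RNA integrity numbers were above 9, and 5.5 ug of single-stranded cDNA was fragmented and labelled with biotin. Groups and replicate numbers were taken from the sample titles.

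The deposited table holds log2 values, 1 per probe set and array, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, equalizes the distributions of the arrays and summarises the probes of each probe set on the log2 scale. Versions, annotation and genome build are not given in the sources used here. The table has 138745 probe sets, of which 2995 are control probe sets. The arrays' medians lay between 3.94 and 3.96 and their upper quartiles between 5.39 and 5.41, and since RMA equalizes the arrays, an overall change in RNA per cell cannot be seen. All 6 arrays reached the same highest value of 19.93, which 67 probe sets had on every array. This is a ceiling, and 17 of the genes tested reached it on at least 1 array. Whether a further transformation followed RMA is not given in the sources used here, and the values spread more widely than RMA values commonly do, so every log2 difference and fold is on the scale of the deposited values and can be larger than on a plain RMA scale. The precision of each value is limited by the number of arrays.

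Probe sets were named from the platform's annotation table, which can be old. It pairs 36176 probe sets with 1 gene symbol and 1119 with several, and does not list 101450, which are unnamed here and were tested only in an alternative. Of the singly named probe sets, symbols were updated through the Entrez ID for 25516, by symbol for 9899 and by synonym for 623 with a RefSeq gene table of GRCh38.p14, and 138 kept the platform's name. No coordinates were taken from that table, since the build of the array's annotation is not given. A gene with several singly named probe sets (1707 genes) was represented by the one with the highest mean over all arrays. Genes with a mean log2 value below 3.93, the median of all probe sets, were left out of the tests, which left 20590 of 33458 genes. Among these, 93 had the same 6 values as another gene, which can come from shared probes.

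The test was limma's moderated test (lmFit and eBayes, limma 3.58.1 in R 4.3.3) on the deposited values, 2-sided, with Benjamini-Hochberg adjustment over the 20590 genes and a threshold of 0.05. The 2 groups were compared without further terms. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over 23 lists, with at least 5 members tested in each. Where camera estimates the correlation instead, it also uses only the residual degrees of freedom of the 6 arrays. A call lost there need not be due to the correlation alone. The lists, the design, the filter and most of the alternatives were fixed before the data were examined. The lists hold 637 genes, of which 576 had a singly named probe set and 494 were tested. List members without a singly named probe set were not analysed here. Where a single value was compared between groups, an exact 2-sided permutation test of the 6 arrays is given; with 3 arrays against 3 it cannot go below 0.1.

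The genes named in the text were chosen by a rule. It takes SMAD3, the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold whose groups do not overlap, filled up by the smallest p in that direction where fewer passed, and up to 4 members with the smallest p in each list. Only symbols found in the gene table were eligible. Other named genes are said to be outside this rule.

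Whether the replicate numbers pair the arrays was checked. The series' design text states that the experiment was done at 3 separate times to give 3 replicates, and the number is taken to mark the time. Across genes, the deviations of same-numbered arrays from their group means correlated at 0.15 for replicate 1, 0.22 for replicate 2 and 0.05 for replicate 3, while arrays of different numbers correlated between -0.18 and 0.06. The value for replicate 3 lay within the range of arrays of different numbers, so its pairing rests on the titles and the design text. The fit with the replicate number as a block is given beside each result whose call it changes.

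The procedure was tested on simulated data. In 20 simulations of this comparison over 20590 genes, with independent noise, 200 genes were changed. At the adjusted threshold, 1.9% of genes changed by 0.5 on the log2 scale were recovered, 38.7% of those changed by 1, 96.3% of those changed by 2 and 98.0% of those changed by 4, with 6.85 false calls per simulation on average. The adjusted threshold is easier to reach where many genes change. These shares hold for 200 changed genes and are likely too high where few genes change. A list shifted by 0.5 was called in 100% of the simulations, and 0.05 other lists on average. Alternatives covered the block, the filter, the centring and scaling of arrays, the choice of probe set, the variance model, array weights, an unmoderated statistic, the thresholds, unnamed probe sets, other list tests and the omission of arrays. The omission of both arrays of one replicate number, and the list tests that combine the block with another method, were added after the data were seen.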

Results

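Transcript levels were compared between TPC-1 cells, a human papillary thyroid carcinoma line, 24 h after transfection with an siRNA against SMAD3 and the same cells after a control siRNA. SMAD3 is a transcription factor that carries signals from TGF-beta and activin receptors to the nucleus. Each group had 3 arrays, from experiments done at 3 separate times. Across the genes tested, the correlation between any 2 arrays lay between 0.986 and 0.992, so no 2 arrays held the same values. The first principal component held 29.3% of the variance and set both replicate 2 arrays (scores of 23.6 in si-Control and 39.5 in si-SMAD3) apart from the other 4 arrays, whose scores lay between -28.1 and -6.15. The question put to the data is which transcripts depend on SMAD3 in these cells.

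SMAD3 mRNA fell in every experiment. Its log2 level was 14.36 ± 0.27 (SD, n = 3) with control siRNA and 10.29 ± 0.28 (SD, n = 3) with SMAD3 siRNA. The values were 14.20, 14.21 and 14.67 in the 3 control arrays and 10.58, 10.03 and 10.27 in the 3 knockdown arrays. The change of -4.06 (SE 0.22, 95% interval -4.56 to -3.57) is a 16.7-fold lower level on the array's scale, with an adjusted p of 0.0014 by limma's moderated test over 20590 genes. The exact permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. Within the 3 experiments the change was -3.62, -4.18 and -4.40.

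**Figure D1:**
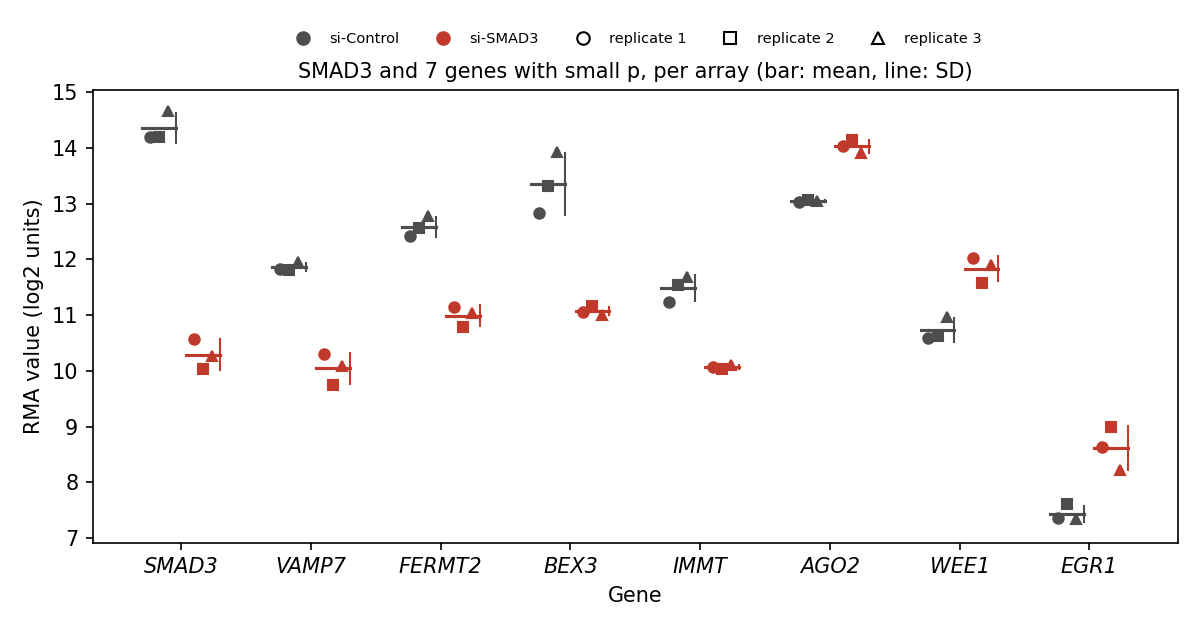
RMA values in log2 units (vertical axis) of SMAD3 and 7 other genes (horizontal axis) in each si-Control array (grey) and si-SMAD3 array (red); marker shapes give the replicate number, horizontal bars the group mean and vertical lines the SD of 3 arrays. SMAD3 lies at 14.36 on average in the control arrays and at 10.29 in the knockdown arrays, and for each gene shown the groups do not overlap.

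SMAD3 was the only one of the 20590 genes to pass the adjusted threshold; no gene rose and no other gene fell past it by limma's test. The next smallest adjusted p was 0.12. With an intensity trend and robust variance in the same test, 5 genes passed, each lower after knockdown, and these were SMAD3, VAMP7, FERMT2, BEX3 and PRKAA1. With an unmoderated statistic 0 genes passed, with 1133 at an unadjusted p under 0.05. At an unadjusted p under 0.05 there were 602 higher and 655 lower genes, together 1257 where chance gives 1029.5 for independent genes. The intensity trend fit gave 1047. Other groupings of the 6 arrays, 3 against 3, gave between 681 and 1587. Those above 1257 (1587, 1465 and 1378) kept both replicate 2 arrays together. The others that, like the real grouping, parted all 3 pairs of same-numbered arrays gave 1053, 992 and 681. These are too few to tell whether 1257 is an excess. At an unadjusted p under 0.001 there were 10 higher and 26 lower genes. The groups did not overlap for 2272 genes, 11.03% of those tested, where chance gives 10%. The median size of the difference over all genes was 0.17 on the log2 scale.

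The 8 genes with the smallest p after SMAD3 were lower in the knockdown arrays and well expressed, with control means between 11.39 and 14.51, and none passed the adjusted threshold. VAMP7, a SNARE of late endosomes and lysosomes, was at 11.87 ± 0.08 in the control arrays and 10.05 ± 0.28 in the knockdown arrays (SD, n = 3), a difference of -1.82. VAMP7 lies in a pseudoautosomal region; another probe set at a mean of 10.35 gave -1.83, and a further one at a mean of 3.11, below the filter, gave -0.03. Probe sets of that region on X and Y can share probes. FERMT2, which encodes the integrin activator kindlin-2, was at 12.58 ± 0.18 and 10.99 ± 0.18 (difference -1.59). BEX3, an adaptor of the neurotrophin receptor p75, was at 13.36 ± 0.55 and 11.08 ± 0.08 (difference -2.28), and IMMT, a scaffold of the mitochondrial inner membrane, at 11.49 ± 0.23 and 10.07 ± 0.03 (difference -1.42). The adjusted p by limma was between 0.12 and 0.17 for these 4 genes. PRKAA1, a catalytic subunit of AMP-activated kinase, differed by -1.25, the calcium-binding protein gene RCN2 by -1.15, the chaperone gene HSPA13 by -1.21, RALGPS2 by -1.06 and the centriolar protein gene CCP110 by -0.98. In the other direction AGO2, the slicer Argonaute of RNA silencing, was at 13.05 ± 0.01 in the control arrays and 14.03 ± 0.12 in the knockdown arrays (difference 0.98, adjusted p = 0.47 by limma). WEE1, the kinase that holds CDK1 inactive, differed by 1.10 and the immediate early transcription factor EGR1 by 1.19. INAVA (1.10), FAM110B (1.08), PRODH (1.17), FGGY (1.23), the vault RNA VTRNA1-1 (1.15) and the pseudogenes RN7SL55P (0.93) and ATP5F1BP1 (0.79) completed the 10 increases. The pseudogene probe sets can take signal from their parent families. ATP5F1BP1 was near the floor, with a control mean of 3.59, below the filter of 3.93, and a knockdown mean of 4.38.

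**Figure D2:**
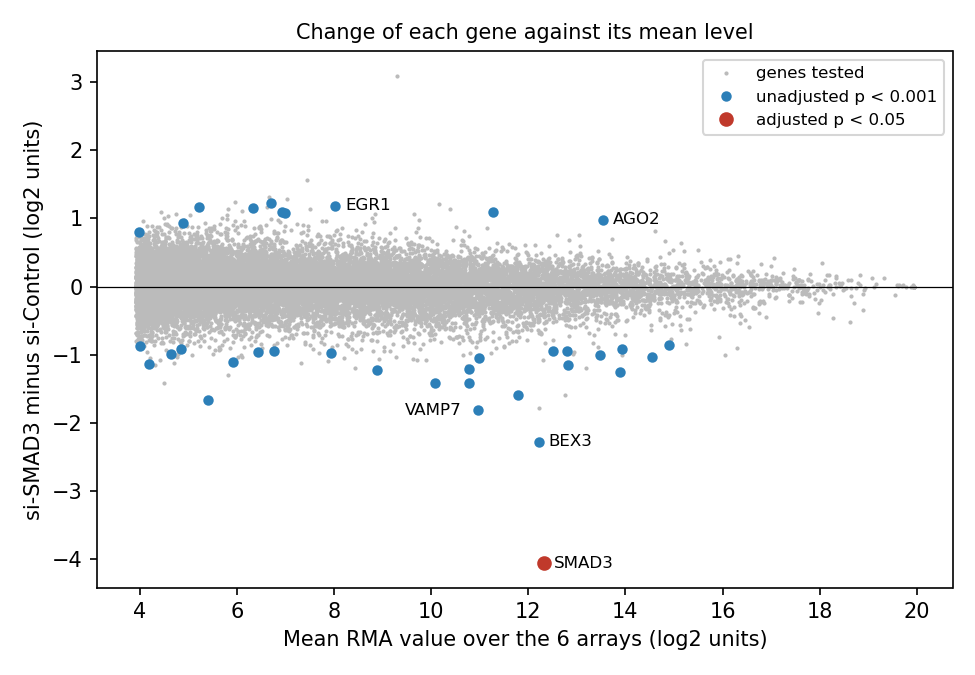
Difference between si-SMAD3 and si-Control in log2 units (vertical axis) against the mean RMA value over the 6 arrays in log2 units (horizontal axis), 1 point per gene for 20590 genes; blue marks an unadjusted p under 0.001 and red an adjusted p under 0.05 by limma. SMAD3 at -4.06 stands alone in red, and together with it 26 marked genes lie below 0 against 10 above.

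Known transcriptional targets of TGF-beta signalling were not called as a group. Of 44 listed genes 38 were tested; 23 lay above and 15 below 0, the mean difference was 0.09 and camera gave an adjusted p of 0.52. None passed, either over all genes or adjusted over the list alone. SMAD3 itself is in none of the 23 lists. The members with the smallest p were RHOB (difference 0.51, SE 0.22), LEMD1 (0.68, SE 0.31), the cell cycle inhibitor CDKN1A (0.68, SE 0.38) and LIMK2 (0.37, SE 0.21). Among textbook targets outside the naming rule, the feedback inhibitor SMAD7 differed by -0.16 (SE 0.18), SKIL by 0.08 (SE 0.19), PMEPA1 by 0.37 (SE 0.39) and CCN2 by -0.27 (SE 0.37). The list mean differed by 0.21, 0.25 and -0.19 in the 3 experiments, and over all settings tried the list's mean difference ran from 0.01 to 0.23, with an adjusted p from 0.16 to 0.95. A single-gene change of 0.5 on the log2 scale was recovered in only 1.9% of simulated cases, so changes of that size in single targets were mostly not detectable with these 6 arrays. A shift of 0.5 of a whole list, that of cholesterol synthesis, was called in 100% of the simulations, which held no variation shared between genes. The sample titles name no added TGF-beta, and the arrays do not measure SMAD3 protein. How active the pathway was in the control cells is therefore not known here.

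Receptors, ligands and other SMADs were likewise not called. Of 31 tested members of the TGF-beta and BMP pathway, 17 lay above and 14 below 0 (camera adjusted p = 0.51), with a mean of -0.06 and a median of 0.04. The members with the smallest p all had lower values in the knockdown arrays: the ubiquitin ligase SMURF2, which acts on SMADs and receptors (difference -0.66, SE 0.17), the BMP type II receptor BMPR2 (-0.75, SE 0.21), the activin antagonist FST (-0.64, SE 0.19) and the TGF-beta type I receptor TGFBR1 (-0.70, SE 0.21). Their adjusted p by limma lay between 0.64 and 0.75, and the smallest p adjusted over the list alone was 0.085. Of other SMADs outside the naming rule, SMAD2, the closest relative of SMAD3, differed by -0.10 (SE 0.16), SMAD4, the partner shared by receptor-activated SMADs, by 0.09 (SE 0.17), SMAD1 by 0.05, SMAD5 by -0.23 and SMAD9 by -0.28. Of 11 tested BMP and ID target genes 5 lay above and 6 below 0 (camera adjusted p = 0.91, mean 0.08, median -0.05), with BAMBI, a pseudoreceptor, at 0.57, SMAD6 at -0.39, HEY1 at 0.84 and ID1 at -0.47.

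Genes of epithelial-mesenchymal transition and of the matrix were not called as groups. Of 23 tested transition genes 10 lay above and 13 below 0 (camera adjusted p = 0.33). CTNNB1, which encodes beta-catenin, was at 15.06 ± 0.26 in the control and 14.03 ± 0.21 in the knockdown arrays (SD, n = 3); its difference of -1.03 was the 1 member past the threshold adjusted over the list alone (0.022), and had an adjusted p of 0.55 over all genes by limma. The integrin gene ITGA5 differed by 0.46, ZEB2 by -0.38 and the tight junction gene OCLN by -0.35. Of 31 tested matrix genes 12 lay above and 19 below 0 (camera adjusted p = 0.62), with COL8A1 at -0.37, the collagen lysyl hydroxylase PLOD2 at -0.46, COL6A1 at 0.78 and LOX at -0.29. Of 20 tested Hippo-YAP targets 8 lay above and 12 below 0, with a mean of -0.22 and a camera adjusted p of 0.077. That list passed with the replicate block (adjusted p = 0.010). It did not with the block and an estimated correlation (adjusted p = 0.95, unadjusted p = 0.076 by camera). It passed without si-Control replicate 2 (mean -0.38, adjusted p = 0.0055) and without si-SMAD3 replicate 1 (mean -0.28, adjusted p = 0.047). The mean was -0.13 without si-Control replicate 1, -0.14 without si-Control replicate 3 and -0.12 without si-SMAD3 replicate 2 (adjusted p = 0.34, 0.21 and 0.31). Both replicate 2 arrays had its lowest means, -0.21 in si-Control and -0.30 in si-SMAD3 relative to the 6 arrays, against -0.05 to 0.28 in the others, and the exact permutation test gave p = 0.3. Its members with the smallest p were the receptor tyrosine kinase AXL at -1.59, DOCK5 at -0.57, IGFBP3 at 0.67 and NUAK2 at -0.34.

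The cell cycle list fell. All 50 of its members were tested, 45 lay below and 5 above 0, the mean difference was -0.29, and camera gave an adjusted p of 1.1e-06. The call is lost when the correlation between members is estimated from the data (adjusted p = 0.92 with an estimated correlation of 0.50). No single member passed over all genes or adjusted over the list alone. The smallest p belonged to the replicative helicase subunit MCM6 (difference -0.95, SE 0.33), CENPF (-0.44, SE 0.16), the mitotic cyclin CCNB2 (-0.52, SE 0.19) and the mitotic kinesin KIF20A (-0.60, SE 0.25). The list mean differed by -0.33, -0.13 and -0.41 within the 3 experiments. Both replicate 2 arrays, which stood apart on the first principal component, had the lowest list means, -0.31 in si-Control and -0.44 in si-SMAD3 relative to the mean of the 6 arrays; the other 4 lay between -0.01 and 0.43. The exact permutation test of the list mean gave p = 0.4. Without the si-SMAD3 replicate 2 array the mean difference was -0.14 and the camera adjusted p 0.058. It was -0.52 without si-Control replicate 2 and -0.14 without si-Control replicate 3. Over all settings tried the adjusted p ran from 3.8e-15 to 0.95.

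**Figure D3:**
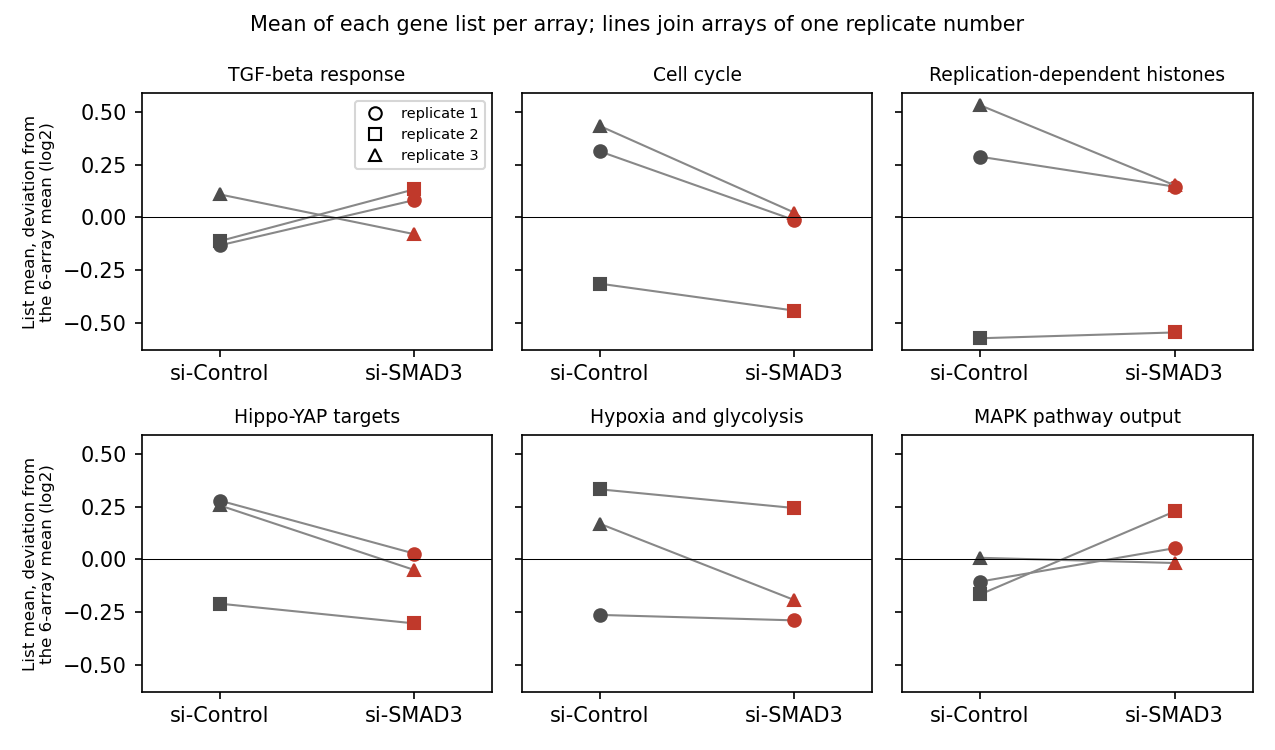
Mean log2 deviation of each gene list's tested members from the 6-array mean (vertical axis) in si-Control and si-SMAD3 arrays (horizontal axis), with lines joining arrays of one replicate number. The cell cycle list is lower in si-SMAD3 in each of the 3 experiments, and in the cell cycle and histone panels both replicate 2 arrays (squares) lie below the other 4.

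Replication-dependent histone genes varied with the same arrays. Of 28 tested, 24 lay below and 4 above 0, with a mean of -0.16; the list mean was -0.57 and -0.54 in the replicate 2 arrays of si-Control and si-SMAD3, against 0.15 to 0.53 in the others. Camera gave an adjusted p of 0.077, 0.0051 with the replicate block, and an adjusted p = 0.95 with the block and an estimated correlation. The list mean turned with single arrays. It was -0.49 without si-Control replicate 2 (adjusted p = 1.5e-09) and -0.28 without si-SMAD3 replicate 1 or 3 (adjusted p = 0.0056 and 0.0027), but -0.06 without si-Control replicate 1, 0.06 without si-Control replicate 3 and 0.07 without si-SMAD3 replicate 2 (adjusted p = 0.74, 0.99 and 0.54). Within the 3 experiments it differed by -0.14, 0.03 and -0.38, and the exact permutation test gave p = 0.6. H2AC12 differed by -0.37, H2BC9 by -0.38, H1-2 by -0.41 and H3C8 by -0.46; histone genes are near-identical copies that probe sets can split wrongly. Of 20 tested p53 targets 13 lay above and 7 below 0 (camera adjusted p = 0.79). The members with the smallest p were the receptor genes EDA2R at -1.10 and TNFRSF10B at 0.49, CDKN1A at 0.68 and the repair gene XPC at -0.23.

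Genes induced by MAPK signalling had mostly higher values after knockdown. Of 24 tested, 16 lay above and 8 below 0, with a mean of 0.18 and a camera adjusted p of 0.077. The list passed only without si-SMAD3 replicate 3 (mean 0.23, adjusted p = 0.033), among all settings tried, had a mean of 0.11 without si-SMAD3 replicate 2 (adjusted p = 0.34), and had an adjusted p of 0.92 with an estimated correlation. Within the 3 experiments the list mean differed by 0.16, 0.39 and -0.02, and the exact permutation test gave p = 0.2. EGR1 (7.43 ± 0.15 against 8.62 ± 0.39) and the feedback inhibitor SPRY4 (9.83 ± 0.23 against 10.96 ± 0.40, SD, n = 3) passed the threshold adjusted over the list alone, not that over all genes (adjusted p by limma of 0.53 and 0.58). The growth factor gene HBEGF differed by 0.67 and ETV1 by 0.44. Of 26 tested NF-kB and cytokine genes 17 lay above and 9 below 0 (camera adjusted p = 0.32); the inhibitor of apoptosis BIRC3 differed by 1.24, complement C3 by 1.22, TNFAIP2 by 0.66 and the chemokine CCL2 by -0.78. Interferon-induced genes can respond to transfected RNA, which both groups received, so a response common to both cannot be seen here. Of 33 tested, 20 lay above and 13 below 0 (camera adjusted p = 0.55), with IRF1 at 0.86, TLR3 at 0.55, IFIT3 at -0.46 and HERC5 at -0.54. The unfolded protein and ATF4 stress list had 14 above and 17 below 0 (camera adjusted p = 0.66), with VLDLR at -0.95 and the chaperone DNAJC3 at 0.50. Heat shock and oxidative stress genes had 8 above and 7 below 0 (camera adjusted p = 0.79, mean -0.05, median 0.02), with the co-chaperone BAG3 at 0.48.

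Among metabolic genes, 22 of 30 tested hypoxia and glycolysis genes lay below and 6 above 0, and GAPDH and LDHA were at the ceiling on all arrays. The list had a mean of -0.16 and a camera adjusted p of 0.051. That list passed with the replicate block (adjusted p = 0.0071) and not with the block and an estimated correlation (adjusted p = 0.95). It also passed without si-Control replicate 1 (mean -0.33, adjusted p = 8.2e-05) and without si-SMAD3 replicate 2 (mean -0.32, adjusted p = 0.00019), while the mean was -0.03 without si-Control replicate 2, -0.05 without si-SMAD3 replicate 1 and -0.10 without si-SMAD3 replicate 3 (adjusted p = 0.60, 0.39 and 0.15). Both replicate 2 arrays had the highest means of this list, 0.33 in si-Control and 0.24 in si-SMAD3 relative to the 6 arrays, against -0.29 to 0.17 in the others. Within the 3 experiments it differed by -0.03, -0.09 and -0.36, and the exact permutation test gave p = 0.6. ANKRD37 differed by -0.58, the oxidoreductase ERO1A by -0.41, the glucose transporter SLC2A1 by -0.53 and the mitophagy receptor BNIP3 by -0.64. Oxidative phosphorylation genes were 15 above and 15 below 0 (camera adjusted p = 0.59); UQCRC2, a core subunit of complex III, was at 15.33 ± 0.18 in the control and 14.55 ± 0.10 in the knockdown arrays (SD, n = 3) with an adjusted p of 0.58 by limma. The cholesterol synthesis list (11 above, 9 below 0) and the ribosomal protein list (8 above, 13 below 0) had camera adjusted p of 0.91 and 0.73, and every tested member had an unadjusted p above 0.05 by limma.

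Thyroid differentiation could be followed only in part, since 7 of the 21 listed genes were above the filter. Of these 6 lay below and 1 above 0 (camera adjusted p = 0.52), with THRB at -0.34, DIO1 at -0.40, the thyroid transcription factor gene FOXE1 at 0.23 and GLIS3 at -0.10. The markers of other cell types were not called. The list means were 4.93 in the control and 4.96 in the knockdown arrays for 6 immune genes, 5.40 and 5.36 for 6 endothelial genes, and 5.92 and 6.03 for 9 fibroblast genes, with camera adjusted p of 0.91, 0.91 and 0.66. For the endothelial genes the mean of -0.03 and the median of 0.00086 differ in sign. Of 11 tested reference genes 6 lay below and 4 above 0, and GAPDH was at the ceiling on all arrays, where no change can be seen. The list had a mean of -0.23 and a camera adjusted p of 0.077, or 0.031 with the replicate block and an adjusted p = 0.95 with the block and an estimated correlation, and its mean was -0.15 without si-Control replicate 3 (adjusted p = 0.25). Within the 3 experiments the list mean differed by -0.16, -0.08 and -0.46. The exact permutation test gave p = 0.1, the smallest that 3 arrays against 3 allow. HPRT1, a purine salvage enzyme often used to normalize, was at 9.46 ± 0.43 in the control and 8.40 ± 0.26 in the knockdown arrays (SD, n = 3). Its difference of -1.06 was the 1 member past the threshold adjusted over the list alone, with an adjusted p of 0.62 over all genes by limma. In the 23 lists no member passed over all genes, and adjusted over the list alone members passed in 3 lists, those of epithelial-mesenchymal transition, MAPK output and reference genes.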

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

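Leaving out both arrays of one replicate number, and the list tests that join the replicate block with another method, were chosen after the data were seen. The level of SMAD3 stayed between -4.29 and -3.90 in the 9 fits that left out arrays. It passed the threshold when any 1 array was left out, and the adjusted p lay between 0.077 and 0.16 when both arrays of a replicate were, where 2 arrays remained per group. With an unmoderated statistic the change was -4.06 with an adjusted p of 0.55, and 0 genes were called, with 1133 at an unadjusted p under 0.05. The count of genes called was 5 with an intensity trend and robust variance and ranged from 0 to 1 over the fits that left out arrays, 0 in each of the 3 that left out a replicate of both groups. It stayed at 1, SMAD3, with the replicate block, the other filters, scalings, thresholds and probe set rules, array weights and all 69373 probe sets above the filter. The lists past the threshold numbered 1 as reported and 5 with the replicate block (cell cycle, Hippo-YAP, histones, hypoxia and reference genes), and the same 5 with an intensity trend. They numbered 2 (cell cycle and hypoxia) without a filter, with the stricter filter, with centred arrays, with the mean of probe sets and with array weights. They ranged from 1 to 4 over the fits that left out arrays, and the cell cycle list was among them in 8 of these 9, the exception being without si-SMAD3 replicate 2. The 4 lists without replicate 2 were cell cycle, Hippo-YAP, histones and reference genes. No list passed (0 of 23) with an estimated correlation or with fry, with or without the block. At an unadjusted p under 0.05 these gave 0 lists without the block, where camera with its preset correlation gave 6. With the block and an estimated correlation the adjusted p was 0.95 for nearly every list, so it does not rank them. By that camera test the unadjusted p was 0.076 for Hippo-YAP, 0.097 for cell cycle and 0.37 for histone genes. The replicate block changed no other call. Among named genes, only VAMP7, FERMT2, BEX3 and PRKAA1 crossed the threshold, each in the intensity trend fit alone. Scalings moved the median of all genes by less than 0.1. With 3 arrays per group, 38.7% of simulated changes of 1 on the log2 scale were recovered where 200 genes changed at once. The adjustment is stricter where fewer genes change, so that share is likely too high here. BEX3, at -2.28, had an adjusted p of 0.16 by limma. The filter left 12868 genes out of the main test. Except where the number of arrays was what differed, the cause was not tested.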

Other observations

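The genes of RNA silencing and the splits of the arrays were chosen after the results were seen; the estimated correlation and the block for the cell cycle list were set before the data were examined, with what each would show written down only afterwards; and the tests on bright genes were chosen after that imbalance was seen, before their own results. Genes of RNA silencing, which no list covered, were looked up after AGO2 was seen, and none of them passed. AGO2 was higher by 0.98, while DROSHA, the nuclear microRNA-processing enzyme, was at 11.73 ± 0.49 in the control and 10.75 ± 0.18 in the knockdown arrays, and TNRC6A, a partner of Argonaute, at 13.43 ± 0.34 and 12.47 ± 0.28 (SD, n = 3). DICER1 differed by -0.40, TNRC6B by -0.49, AGO3 by -0.28, AGO1 by -0.12, AGO4 by 0.18, TNRC6C by 0.02 and XPO5 by 0.03. The smallest adjusted p among these genes was 0.47 by limma, for AGO2.

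Decreases with an unadjusted p under 0.001 that the naming rule left out, named after their values were seen, included several well expressed genes. IL6ST, the shared signalling subunit of the interleukin 6 receptor family, was at 13.98 ± 0.25 in the control and 12.98 ± 0.13 in the knockdown arrays (SD, n = 3). The cullin gene CUL5 differed by -0.94, the chromatin remodelling subunit gene SS18 by -0.92, PDLIM5 by -0.95, the splicing regulator gene PTBP3 by -0.86 and GOLPH3L by -1.42. None of these passed the adjusted threshold by limma.

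SMAD3 was the only gene called. Of the 10 ways to split the 6 arrays 3 against 3, only the real 1 called a gene (1 gene, against 0 as the highest of the others), and 10 splits are too few for a share under 0.05.

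The fall of the cell cycle list rests on how its members' shared variation is treated. In 8 of the 10 splits at least as many lists passed camera's threshold as in the real one. The real split had 1 list and the highest of the others 7, which points to a structure of the samples. This count takes any list, so it does not test the cell cycle list itself. The 4 splits that kept both replicate 2 arrays together gave 4 to 7 lists. Those that parted all 3 pairs gave 1 in the real split and 2, 2 and 0 in the others. The cell cycle list's mean difference, without its sign, was 0.288 in the real split. It was 0.014, 0.203 and 0.071 in the others that parted all 3 pairs. The splits that kept both replicate 2 arrays together gave 0.295, 0.488, 0.511 and 0.214. The remaining splits gave 0.009 and 0.094. Members that vary together but are counted at the preset correlation of 0.01 are a candidate explanation of the call. With the correlation estimated, camera's adjusted p was 0.92 at an unchanged mean. That test also takes fewer degrees of freedom, so the correlation was not changed alone. An offset shared by both arrays of an experiment cancels in the mean by design, but a difference between the experiments in other respects stays open, since with the replicate block camera's adjusted p was 1.2e-09 at the preset correlation, 0.95 at an estimated one and 0.51 by fry, and the mean within-experiment difference of -0.29 had a 95% interval of -0.65 to 0.07; 10 splits are too few for a share under 0.05. A slower cell cycle after loss of SMAD3 stays open too and was not tested.

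Among genes with a mean log2 value of at least 8, decreases outnumbered increases at an unadjusted p under 0.01, 99 to 18 among 7705 genes (a ratio of 5.5), while the 12885 dimmer genes gave 63 decreases and 91 increases; the ratio was 2.07 without si-Control replicate 3 and 3.21 without si-SMAD3 replicate 3. After each array's trend of deviation on mean level was removed, the ratio was 5.72 (103 to 18). The 95% exact binomial interval for the share of decreases was 77.5 to 90.9%, as if genes were independent. This argues against a broad intensity-dependent shift between arrays as the whole cause. The trend was fitted over all probe sets, most of them dimmer than 8, so it follows the bright range only coarsely. A shift within that range stays open. A difference between the 3 experiments stays open: the ratio was 4.33 with the replicate block (104 to 24), past the bound of 2 set beforehand, but with balanced pairs the block leaves each gene's difference as it was, so that bound could not decide. Another grouping of the arrays stays open too, since 2 of 10 splits gave as large a difference between decreases and increases, 81 genes in the real one and 102 in the highest other, which kept both replicate 2 arrays together; the other splits that parted all 3 pairs gave 31, 14 and 5, and 10 splits are too few for a share under 0.05. Unintended silencing by the siRNA, which may lower transcripts without raising others, and loss of SMAD3 itself were not told apart, since no siRNA sequence was used here.

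The gene with the largest difference upward, MIR548AI, was at 7.74 ± 4.30 in the control and 10.84 ± 1.03 in the knockdown arrays (SD, n = 3), a difference of 3.09 within the spread of the control arrays, with an adjusted p of 0.86 by limma. A pair of probe sets unnamed here, chosen after their values were seen, had differences of 2.38 (SE 0.32, TC1500007559.hg.1) and -2.21 (SE 0.29, TC0800011807.hg.1), with adjusted p of 0.50 and 0.41 by limma.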
